A study of Mus musculus with 2 samples.

How the data were processed

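Cells from the endothelial surface of the aorta of 1 young and 1 old mouse had been released with trypsin for 10 minutes and scraping. From each animal 8700 cells were loaded with a target of 5000, and libraries were made with version 2 of a droplet 3′ kit, per the labels' protocols. The deposited files hold whole-number UMI counts per gene and barcode, not normalized, for the same 27998 gene names in both libraries. Per the submitters' processing notes the authors used Cell Ranger and the GRCm38 mouse genome, and the version and gene annotation are not given in the sources used here. The counts were checked to be whole numbers. The lowest barcode held 2287 UMIs in young and 1541 UMIs in old, so the files hold barcodes already called as cells.

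Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left out 1 young and 72 old barcodes. Scrublet, run per library within scanpy 1.11.5, called 5 young and 4 old barcodes as doublets (0.366% and 0.120%), which were removed. So few calls mean that it did not work as a doublet filter here. A marker rule applied to each cell was tried as an alternative. It keeps a doublet that holds more endothelial markers than markers of any other class, so it does not settle the part of doublets. The 1360 young and 3332 old cells were normalized to 10000 UMIs, log-transformed and clustered together without batch correction (genes seen in at least 3 cells, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 0.5). Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9.

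Each cluster was named after the class whose fixed markers were seen in the largest mean share of its cells, if at least 3 of them were seen in 25% of its cells. It stayed unnamed where another class had more markers among its top 10 genes by fold. That fold was taken against cells of clusters with another name. Against all other cells, clusters split by library within the endothelial class are led by genes that part those clusters, among them Mylk, a marker of smooth muscle. This choice was made after seeing the clusters. The markers Trac, Trbc2, Ighm, Ighd and Igkc are missing from the files under these names. The T or NK-like cluster also carried B cell markers (Ly6d, Cd79a, Cd79b, Ms4a1), so it mixes in B cells.

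UMIs were summed over the cells of a class in each library and scaled to the class total of each library (CPM). The log2 ratio of old over young carries an exact conditional binomial 95% interval for the ratio of 2 Poisson counts. Shares carry exact Clopper-Pearson 95% intervals. With 1 library per age no test between ages was made, and intervals cover counting error only, not the spread between animals. A gene list is given as the median log2 ratio of its members with at least 20 UMIs in both libraries together. Beside it stand a 95% interval from 1000 Poisson redraws of the counts and its percentile among 10000 random lists of equal size matched on expression in 20 bins. Members with 0 UMIs in 1 library were set at 3 counts.

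Lists, markers and the rule for named genes were fixed before the data were examined. The rule takes the 12 highest and 12 lowest ratios in EC-like cells, ranked by the interval bound nearest to a ratio of 1, among genes with at least 100 UMIs. It leaves out mitochondrial, ribosomal protein, haemoglobin, unnamed-model, Xist, Tsix and Y-linked genes. Genes whose CPM in another class of at least 20 cells was over 3 times that in EC-like cells were reported apart as possible free RNA, and list members that meet this criterion are marked as such. It adds the 2 highest and 2 lowest members of each list, and 5 each way for fibroblast-like cells. A gene of the lowest 12 and a list member that the rule picks are left out of the text and figures. Eln, Pecam1, Isg15, Ccl7 and the fibroblast-like values of list members fall outside it and were chosen after their values were seen, as were the genes shown at equal depth.

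For shares of cells with a UMI, each cell was thinned to 3100 UMIs, the 25th percentile of the old EC-like cells rounded down to a multiple of 100, and shallower cells were left out. The Fano factor used genes with a mean of at least 0.1 UMI per thinned cell in both libraries and equal numbers of cells.

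Coordinates are those of GENCODE vM21 on GRCm38, matched by gene name. To find genes that may share reads, the 50-mers of the last 500 bases of each gene's transcripts were searched in the transcripts of every other gene of that annotation, for 12739 of 13122 expressed genes (97.1%). This search was added after seeing the data.

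The ratio and interval code was tested on simulated counts for 9935 real genes of the EC-like comparison with genes altered by known folds. Summed counts were drawn from Poisson, the model that the interval assumes, with no spread between cells. This checks the code only, and intervals can be too narrow for genes whose UMIs lie in few cells. The interval held the true ratio for 95.4% of unaltered genes. It held it for 93.2% of 44 genes at 0.25-fold, 100% of 47 at 0.5-fold, 96.0% of 50 at 2-fold and 100% of 50 at 4-fold. Alternatives tried were a stricter cell filter (at least 500 genes, at most 5% mitochondrial UMIs), no filter, doublet calls kept, Leiden resolution 1.0, the per-cell marker rule (at least 2 endothelial markers and more than of any other class), and the mean of per-cell CPM. Others were median-of-ratios scaling, other UMI minimums for list members (100, or 1 in each library), thinned counts, totals without mitochondrial, ribosomal and haemoglobin genes, the squared coefficient of variation, and unthinned shares.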

Results

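The endothelial lining of the mouse aorta was profiled cell by cell in 1 young mouse (8 weeks) and 1 old mouse (18 months) of the C57BL6/J strain. Endothelium was freed with trypsin and a fine blade, and its RNA was counted with a droplet method that tags the 3′ end of each transcript with a unique molecular identifier (UMI). The young library held 1366 barcodes with 12576023 UMIs, a median of 7558.5 UMIs and 2694 genes per barcode. The old library held 3408 barcodes with 19171045 UMIs, a median of 4737 UMIs and 1951 genes per barcode. Each age rests on 1 library and 1 animal, so no difference between them has a replicate check. All 95% intervals below cover counting error only, and values are given as higher or lower in these 2 libraries.

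The first comparison concerned which cells the preparations held. Endothelial-like (EC-like) cells, which carried Pecam1, Cdh5 and other endothelial markers, were 1083 of 1360 young cells (79.6%, exact 95% interval 77.4 to 81.7%) and 2392 of 3332 old cells (71.8%, 70.2 to 73.3%). Fibroblast-like cells were 17.6% of young cells (15.7 to 19.8%) and 17.4% of old cells (16.1 to 18.7%). Immune and erythroid classes made up more of the old library. Monocyte or macrophage-like cells, led by C1qc, Lyz1 and Lyz2, were 13 young cells (0.956%, 0.510 to 1.63%) and 158 old cells (4.74%, 4.05 to 5.52%). T or NK-like cells, led by Ms4a4b, Cd3g and Nkg7, were 9 young cells (0.662%, 0.303 to 1.25%) and 117 old cells (3.51%, 2.91 to 4.19%), and B cell markers were seen in this class, Cd79a and Cd79b in 26.5% of its old cells each. Erythroid-like cells were 1 young cell (0.0735%, 0.00186 to 0.409%) and 37 old cells (1.11%, 0.783 to 1.53%). A cluster of 14 young and 49 old cells mixed smooth muscle genes (Myh11, Cnn1, Acta2) with endothelial markers and stayed unnamed, at 1.03% and 1.47% of cells. The endothelial share depended on whether clusters led by Coch and Sost kept their name. With a stricter cell filter 1 such cluster lost it, since Mylk was its only leading marker of any class, and the young share became 49.2%. With doublet calls kept the shares became 45.0% and 58.3%. When all clusters were named by marker detection alone, a choice made after seeing the data, the shares were at least 80.3% and 73.2%. With doublet calls kept, this naming also counted as endothelial a cluster of 15 young and 56 old cells led by Myh11 and Cnn1.

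**Figure D1:**
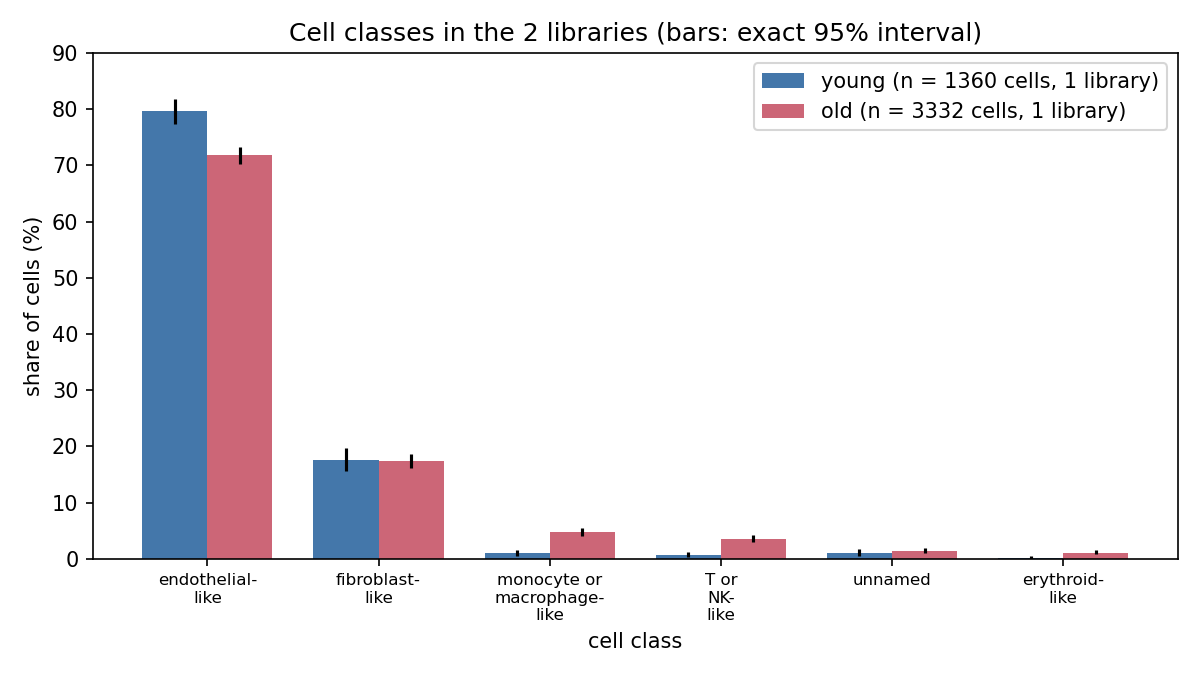
Share of cells (y axis, %) in each cell class (x axis) in the young and the old library, with exact 95% binomial intervals as error bars. The endothelial-like bars stand at 79.6% and 71.8%, and the monocyte or macrophage-like bars at 0.956% and 4.74%.

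The main question was how expression differed between old and young aortic endothelial cells. Genes of MHC class II antigen presentation were higher in old EC-like cells, and immediate early and extracellular matrix genes were lower. Depth differed, with a median of 7396 UMIs per young and 5011.5 per old EC-like cell, so UMIs were summed over cells and scaled to the class total of each library (CPM). The sums were 10094563 UMIs in young and 14152271 UMIs in old EC-like cells. Over 10035 genes with at least 100 UMIs the median log2 ratio of old over young was 0.07. Different clusters held most of the EC-like cells of each library: clusters 0 and 1 were mostly young and clusters 2, 4 and 6 mostly old.

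All 7 measured members of the MHC class II list, which present antigen to CD4 T cells, were higher in old. The list's median log2 ratio was 2.94 (95% interval 2.81 to 3.18), at percentile 100 of 10000 random lists matched on expression. Cd74, the invariant chain (chromosome 18, 60803848 to 60812652, GRCm38), stood at 46.5 CPM in young and 784 CPM in old EC-like cells, a log2 ratio of 4.08 (3.94 to 4.21). H2-Eb1 (chromosome 17, 34305867 to 34316674) stood at 24.7 and 253 CPM, a log2 ratio of 3.36 (3.17 to 3.55). The lowest ratios of the list were 2.43 (2.21 to 2.66) for H2-DMb1 and 1.94 (0.83 to 3.24) for Ciita, the class II transactivator, on 8 and 43 UMIs. H2-DMb1 shared 27.4% of its 3′ sequence with other genes. H2-Ab1 stood at 3.20 and H2-Aa at 2.94. Another class held over 3 times more of every member, for Cd74 monocyte or macrophage-like cells at 17629 CPM, so all 7 met the fixed criterion for possible free RNA. With each cell thinned to 3100 UMIs, Cd74 was seen in 8.55% of young EC-like cells (6.88 to 10.5%) and 63.0% of old ones (60.8 to 65.2%), against 16.0% and 71.4% before thinning. Thinning used 982 young and 1828 old EC-like cells and left out the shallower ones. In fibroblast-like cells, with median depths of 8446 and 4850 UMIs, the thinned shares for Cd74 were 1.79% (0.491 to 4.53%) and 27.7% (23.8 to 32.0%). The macrophage gene Lyz2 was seen in 13.2% of old EC-like cells and 14.5% of old fibroblast-like cells. The EC-like list median was 2.10 under a marker rule applied to each cell.

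**Figure D2:**
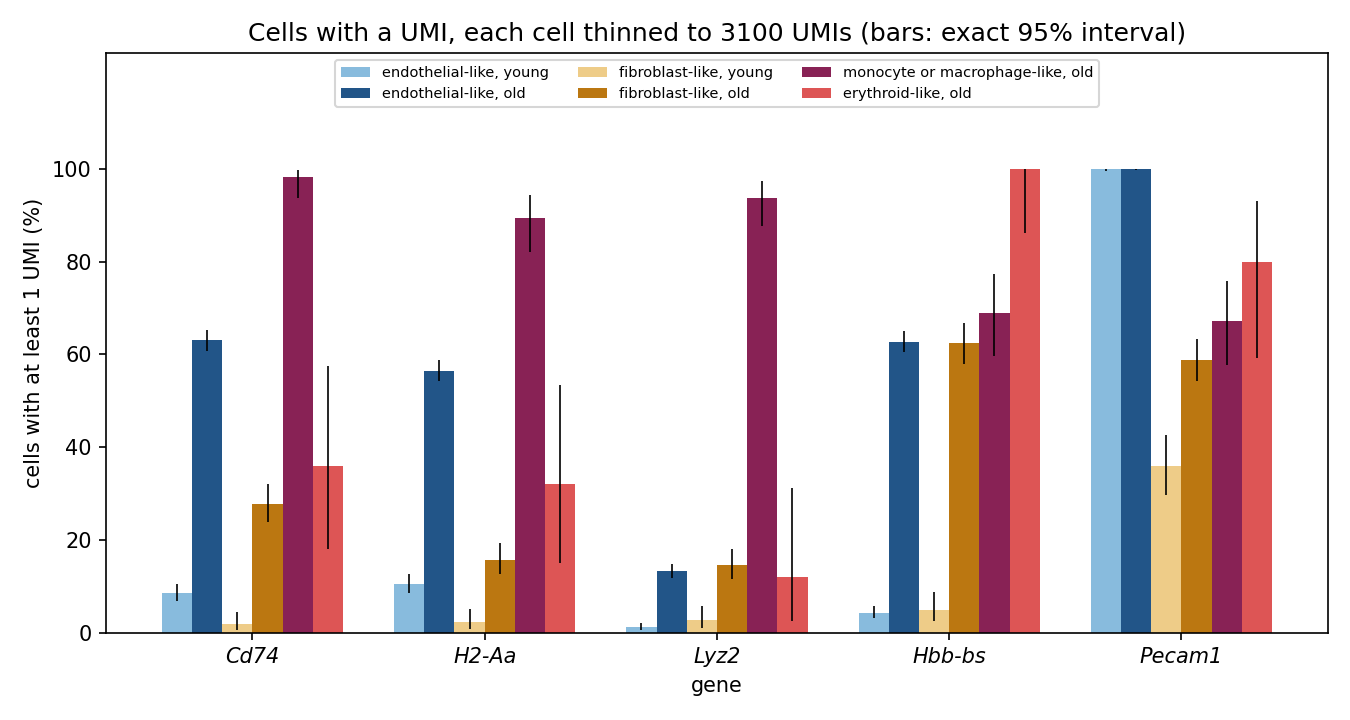
Share of cells with at least 1 UMI (y axis, %) for 5 genes (x axis), by cell class and library, after thinning each cell to 3100 UMIs, with exact 95% intervals as error bars. In the old library Cd74 stands at 63.0% in endothelial-like and 27.7% in fibroblast-like cells, while Lyz2 stands at 13.2% and 14.5%.

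MHC class I genes, which present antigen on most cells, had a smaller ratio: the median over 15 members was 0.25 (0.22 to 0.28), at percentile 99.4 of the random lists, with 12 members higher. H2-Q7 and Psmb8 were highest at 0.52 each, while H2-Q4 stood at -0.61 and Tap2 at -0.31. H2-Q4 shared 27.5% of its 3′ sequence with other genes, so its count is uncertain. The interferon-stimulated list was near the all-gene median at 0.06 (-0.01 to 0.12), with 15 of 24 members higher. Ifitm3, which restricts virus entry, stood at 1502 CPM in young and 2405 CPM in old (log2 ratio 0.68) and Ifi44 at 0.64, while Usp18 stood at -1.16 and Stat2 at -0.27.

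Every one of the 18 measured immediate early and dissociation stress genes, which respond within minutes to signals or handling, was lower in old EC-like cells. The list median was -1.15 (-1.22 to -1.11), at percentile 0.00 of the random lists. Fos (chromosome 12, 85473890 to 85477273) stood at 872 CPM in young and 219 CPM in old, a log2 ratio of -1.99 (-2.05 to -1.93). Cyr61, a matricellular target of YAP, stood at 978 and 243 CPM, a ratio of -2.01 (-2.07 to -1.95), and Atf3 at -3.11 (-3.35 to -2.88). The smallest ratios were those of Ier2 at -0.37 and Myc at -0.07. At equal depth, Fos was seen in 58.4% of young (55.2 to 61.5%) and 36.8% of old EC-like cells (34.5 to 39.0%), and unthinned in 71.3% and 45.6%. In fibroblast-like cells the shares for Fos at equal depth were 74.9% and 66.2%.

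Of 26 measured extracellular matrix and TGF-beta response genes, 20 were lower in old EC-like cells, with a list median of -0.57 (-0.61 to -0.46) at percentile 0.00. Eln, the elastin gene, stood at 2272 CPM in young and 877 CPM in old, a log2 ratio of -1.37 (-1.40 to -1.34). Sparcl1 stood at -2.72 (-3.87 to -1.72) on 47 and 10 UMIs and Col3a1 at -1.68 (-1.84 to -1.52), while Tgfbi stood at 0.21 and Fbn1 at 0.17. Another class held 15 of the 26 at over 3 times the CPM, Col3a1 by fibroblast-like cells at 3216 CPM in young. Without those members the median over 11 genes was -0.43.

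Arterial identity and Notch genes, with 15 of 17 members lower, had a median of -0.30 (-0.36 to -0.24, percentile 0.03). Fbln5, an elastic fibre protein, stood at 1559 CPM in young and 600.0 CPM in old (log2 ratio -1.38, -1.42 to -1.34). It was a gene of the first of 2 EC-like subpopulations described below, at 2426 CPM there in young and 1278 CPM in old. In the second it stood at 777 and 391 CPM, so the ratio over all EC-like cells also reflects the mix of subpopulations. The Notch target Hes1 stood at -1.17 (-1.27 to -1.06). The Notch ligand Dll4 was higher at 0.60 (0.37 to 0.83), and Jag2 stood at 0.16. Circadian clock genes had a median of -0.28 (-0.35 to -0.19, percentile 0.05), with 10 of 14 lower. Ciart stood at -1.28 (-1.61 to -0.96) and Bhlhe40 at -1.06, while Cry1 stood at 0.72 and Clock at 0.54. The labels give no time of day for either preparation. Shear-responsive and vasodilator genes had a median of -0.15 (-0.22 to -0.13, percentile 4.25). The vasoconstrictor gene Edn1 stood at 355 CPM in young and 162 CPM in old (-1.13) and Klf4 at -0.40, while Hmox1 stood at 0.60 and Nqo1 at 0.23.

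Nuclear genes of oxidative phosphorylation were slightly higher in old, with 24 of 28 members higher, a median of 0.21 (0.17 to 0.22) and percentile 99.9. Ndufb8 stood at 0.46 and Atp5g1 at 0.43, while Ndufa1 stood at -0.49 and Sdhc at -0.21. Mitochondrially encoded genes had a median of 0.19 (0.16 to 0.22, percentile 95.2), with mt-Co3 at 0.64 and mt-Co1 at 0.52 but mt-Nd3 at -0.84 and mt-Atp8 at -3.10. Of these, mt-Co3, mt-Co1 and mt-Nd3 shared at least 95.3% of their 3′ sequence with other genes, and Atp5g1 45.9%. Mitochondrial genes together held 21741 CPM in young and 27918 CPM in old.

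The other lists had medians from -0.08 to 0.16, apart from the venous list. Senescence and growth arrest genes had a median of 0.10 (-0.09 to 0.24, percentile 64.8). Ccnd1 stood at 1.04 and Cdkn1a, the p21 gene, at 0.72 (0.47 to 0.98), while Igfbp7 stood at -0.74. Another class held 11 of the 18 at over 3 times the CPM, Cdkn1a and Igfbp7 among them. Leukocyte adhesion and chemokine genes had a median of 0.02 (-0.14 to 0.15). In 2 EC-like subpopulations, a split made after seeing the data, it was -0.29 (-0.38 to -0.16) over 11 members and 0.29 (0.05 to 0.50) over 15 members. Without 6 members held at over 3 times the CPM by another class, Ccl2 and Cxcl1 among them, it was -0.14. Cxcl9 had 0 UMIs in young and 74 in old, held by 0.376% of old EC-like cells, and Ccl2 stood at 3.12 (1.82 to 4.79) on 5 and 61 UMIs, while Cxcl1 stood at -1.38 and Csf1 at -0.48. NF-kB pathway genes had a median of 0.13, with Nfkbie at 0.62, Bcl3 at 0.57, Nfkbiz at -1.75 and Tnfrsf1a at -0.20. Junction and barrier genes had a median of 0.00 (-0.08 to 0.07), with Jam2 at 0.30, Tjp1 at 0.19, Emcn at -1.24 (-1.39 to -1.09) and Jam3 at -0.72. Haemostasis genes had a median of 0.01, with Plat, the tissue plasminogen activator gene, at 0.88 (0.77 to 0.99), F8 at 0.73 and F3 at -1.90. Plat stood at 29.3 CPM in young and 54.1 CPM in old in the first subpopulation, and at 152 and 209 CPM in the second. Angiogenic and VEGF response genes had a median of -0.06, with Nrp2 at 1.51, Kdr at 0.80, Robo4 at -1.14 and Pdgfb at -0.98.

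Proliferation genes had a median of 0.14 (-0.02 to 0.20), with H2afz at 0.49, Tyms at 0.38, Pcna at -0.84 and Ube2c at -0.35. Mesenchymal transition genes had a median of -0.01, with Myl9 at 1.09, Snai2 at 0.48, Twist1 at -0.96 and Fn1 at -0.68. Fatty acid handling genes had a median of 0.16, with 0 young and 34 old UMIs for Gpihbp1, Tcf15 at 1.78, Fabp5 at -0.34 and Lpl at -0.29. Glycolysis genes had a median of -0.08, with Ldhb at 1.29, Pkm at 0.19, Pgk1 at -2.53 and Slc2a1 at -1.15. Antioxidant defence genes had a median of 0.15 (percentile 92.6), with Hmox1 at 0.60, Gclc at 0.58, Sod3 at -0.74 and Txn1 at -0.27. Heat shock genes had a median of -0.01, with Hsp90aa1 at 0.30, Hspa8 at 0.15, and Dnajb1 and Hsph1 at -0.55 each. Proteasome genes had a median of 0.09, with Psmd4 at 0.39, Psmb3 at 0.38, Psmb7 at -0.23 and Psma5 at -0.15. The venous list had 4 measured members and a median of 0.69 (0.05 to 1.03), with Nr2f2 and Nrp2 at 1.51 each, on 10 and 5 young UMIs, Selp at -0.14 and Ephb4 at -0.33. That median turned negative under 10 alternatives, and the summed CPM of 6 lymphatic endothelial markers in EC-like cells was also higher in old (40.1 in young, 108 in old). Among the genes named here, Nrp2, Nr2f2, Selp, Jam2, Csf1, Robo4, Kdr, Snai2 and Ccl2 had an interval clear of 0 and changed sign under at least 1 alternative. Possible free RNA by the same criterion were Nr2f2, Nrp2, Hmox1, Jam3, F3, Nfkbie, Bcl3, Nfkbiz, H2afz, Tyms, Ube2c, Myc, Atf3, Tgfbi, Fbn1, Sparcl1, Myl9, Fn1 and Lpl. Counts of H2afz, Pcna, Ldhb, Pkm, Hsp90aa1, Hspa8, Psmb3, Psma5, Ifitm3 and Ciart are uncertain, since each shares over 10% of its 3′ sequence with other genes.

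**Figure D3:**
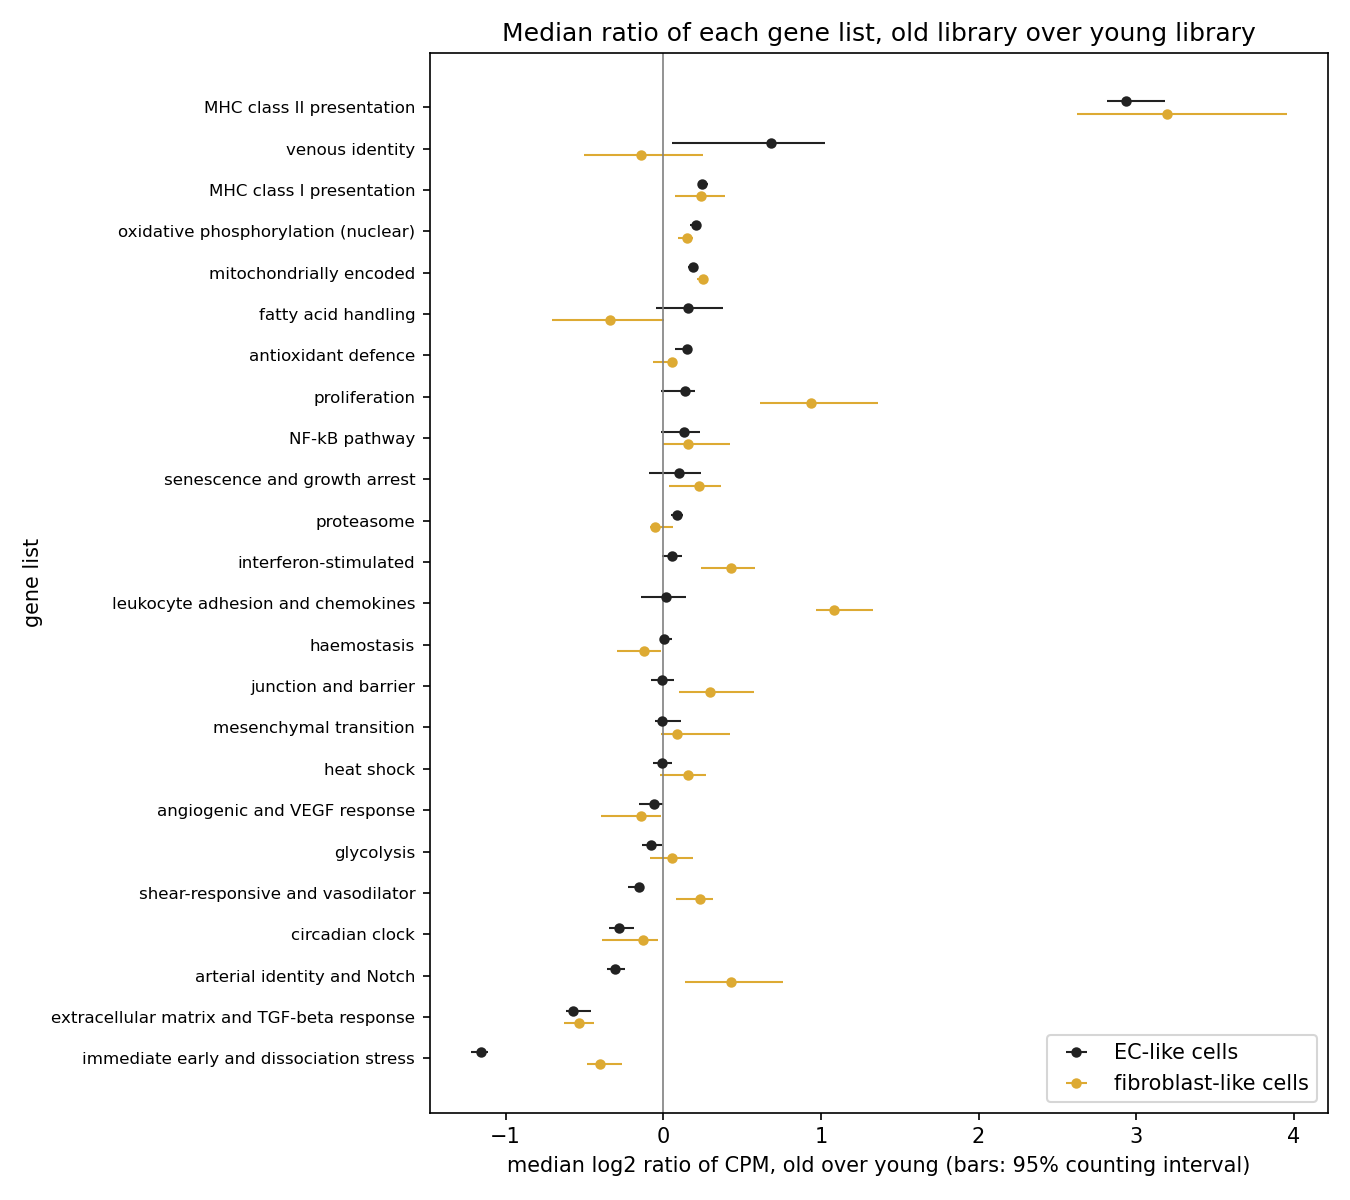
Median log2 ratio of CPM, old over young (x axis), for each gene list (y axis) in endothelial-like and fibroblast-like cells, with 95% counting intervals as bars. The MHC class II list stands at 2.94 and 3.20, and the immediate early list at -1.15 and -0.40.

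Among single genes outside the lists, the highest ratios in old EC-like cells included a pair of retinoic acid enzymes. Cyp26b1, which degrades retinoic acid (chromosome 6, 84571414 to 84593908), stood at 0.495 CPM in young and 19.6 CPM in old, a log2 ratio of 5.31 (4.07 to 6.94) on 5 and 278 UMIs. Aldh1a2, which makes retinoic acid (chromosome 9, 71215789 to 71296243), stood at 2.67 and 50.7 CPM, a ratio of 4.25 (3.69 to 4.86). At equal depth Aldh1a2 was seen in 0.611% of young (0.225 to 1.33%) and 11.2% of old EC-like cells (9.75 to 12.7%), and unthinned in 1.57% and 17.5%. Its share at equal depth was 2.31% (1.16 to 4.10%) in old fibroblast-like cells and it was seen in 17 of 113 old monocyte or macrophage-like cells, which held 61.9 CPM. Kif5c, a kinesin motor gene, stood at 3.69 (3.08 to 4.36), Lrg1 at 3.80 (2.63 to 5.27) and Rspo1, a Wnt signalling enhancer, at 3.50 (2.63 to 4.53). Bcan, the proteoglycan brevican, stood at 14.4 CPM in young and 104 CPM in old (2.85, 2.60 to 3.11), and the matrix gene Abi3bp at 2.40 (2.14 to 2.67). The kallikreins Klk1b21 and Klk1 stood at 3.01 and 2.52, Gucy1a3, a subunit of soluble guanylate cyclase, at 2.83, and Csprs at 3.88. Klk1b21 shared 35.7% and Klk1 27.5% of its 3′ sequence with another gene, while Gucy1a3 and Csprs had no searched sequence. In fibroblast-like cells Csprs (0 young and 34 old UMIs), Bcan (1 and 40) and Aldh1a2 (4 and 25) were also higher in old. The intervals of the other genes named in this paragraph held 0 in that class. Ppbp, a platelet chemokine gene, had 0 young and 124 old UMIs, but these lay in 0.334% of old EC-like cells. It was at least 23.6-fold higher by its exact interval, and 29.5-fold higher with young set at 3 counts. With doublet calls kept, 4 old UMIs and 0 young UMIs remained in the class, which had then also lost the cluster led by Coch and Sost.

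The lowest ratios in old EC-like cells were those of P4ha3, Vps8 and Popdc3. P4ha3, a collagen prolyl hydroxylase subunit, had 106 young UMIs and 1 old UMI, a log2 ratio of -7.22 (-12.53 to -4.71). Vps8 (chromosome 16, 21423118 to 21644680) stood at 207 CPM in young and 14.3 CPM in old (-3.86, -4.07 to -3.65), and Popdc3 at -3.57 (-4.62 to -2.66). Nme2 stood at -3.28, the histone gene Hist2h2aa1 at -3.02, Btg3 at -2.65, Pgk1 at -2.53 and the non-coding Snhg9 at -2.41. The kinase gene Sik1 stood at -2.53 (-2.81 to -2.26). Nme2, Hist2h2aa1, Pgk1 and Btg3 share 3′ sequence with other genes (98.9%, 100%, 40.0% and 28.6% of it), so their counts are uncertain. Several of these stood as low in fibroblast-like cells: Nme2 at -3.25, Vps8 at -3.40, Btg3 at -2.90 and Snhg9 at -2.83.

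**Figure D4:**
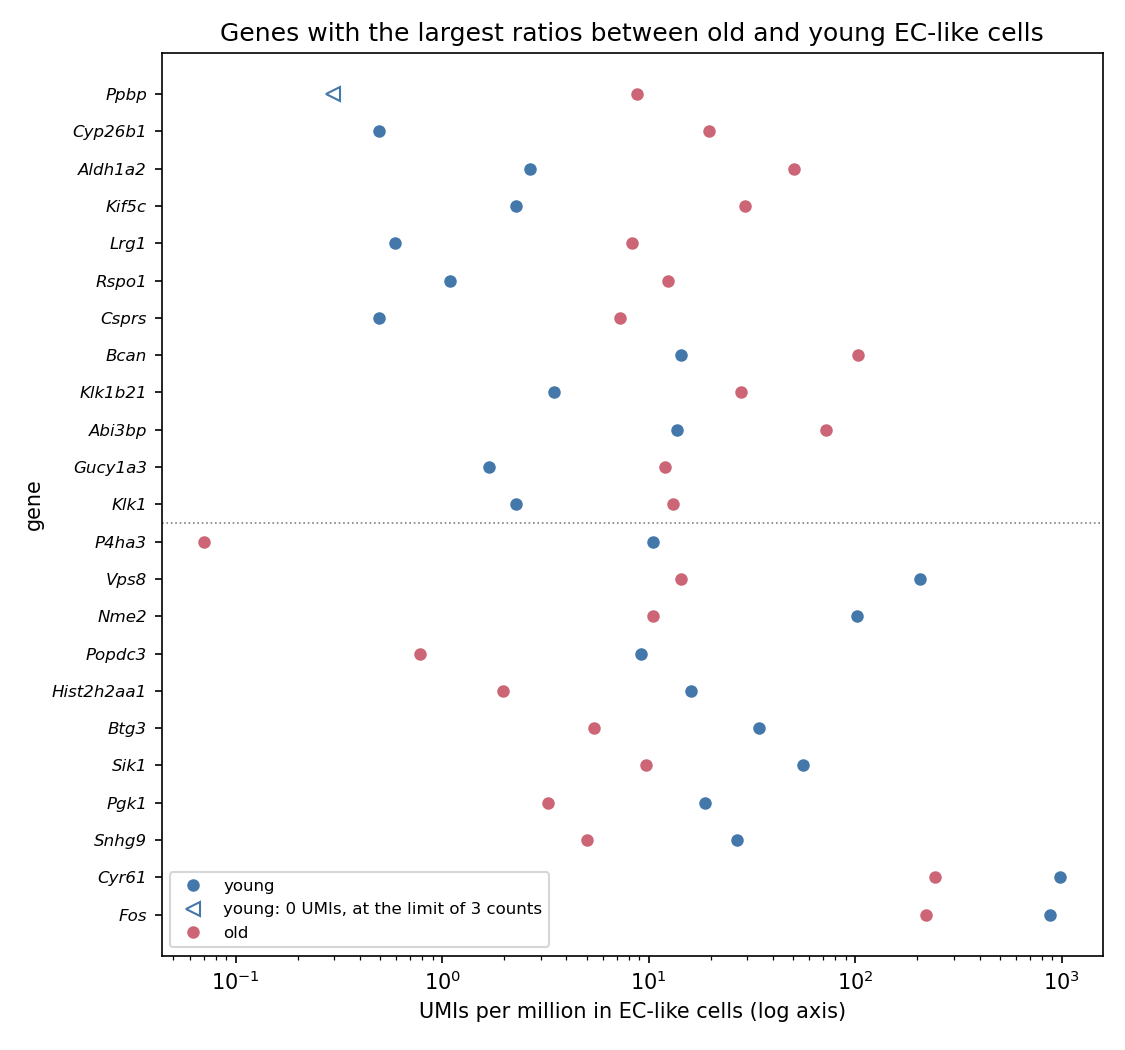
CPM (x axis, log scale) in endothelial-like cells of the young and the old library for the genes with the highest and the lowest ratios (y axis). An open triangle marks a gene with 0 UMIs at the limit of 3 counts. Cyp26b1 stands at 0.495 and 19.6 CPM, and Fos at 872 and 219 CPM.

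Genes held mainly by other classes were set apart as possible free RNA. Macrophage genes were higher in old EC-like cells, with C1qa at 0.693 CPM in young and 19.9 CPM in old (log2 ratio 4.84, 3.78 to 6.17) and Lyz2 at 5.45 and 44.7 CPM (3.03, 2.64 to 3.46). In old fibroblast-like cells they stood at like levels, 18.4 CPM for C1qa and 42.7 CPM for Lyz2. Haemoglobin genes together held 25.2 CPM in young and 604 CPM in old EC-like cells. Hbb-bs was seen at equal depth in 62.7% of old EC-like cells and 62.4% of old fibroblast-like cells. C1qc (4.87), Wfdc17 (4.44), Pf4 (4.11), C1qb (3.93), Tyrobp (3.91) and Ccl6 (3.52) were likewise higher. Lower in old in that set were Spc24 (-2.09), Smpd3 (-1.93), Hist1h2ap (-1.85, with 93.1% of its 3′ sequence shared), Csrnp1 (-1.81), Col1a2 (-1.56), Sfrp2 (-1.48) and Ackr3 (-1.19).

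In thinned counts, the typical gene varied from cell to cell close to the Poisson level in both libraries. Over 4065 genes, at 3100 UMIs per cell and 982 cells from each library, the median Fano factor (variance over mean) was 1.02 in young and 1.02 in old, a ratio of 0.992 (0.991 to 0.997 over redrawn cells). The median squared coefficient of variation was 4.34 in young and 4.15 in old. The Fano factor was higher in old for 43.8% of the genes. Thinning moves the Fano factor towards 1, so values near 1 cannot decide whether cells vary alike in the 2 libraries.

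Fibroblast-like cells, with 240 young and 579 old cells, were compared in the same way. A cluster led by F3, Gdf10 and Mfap4 among other genes held 110 of the young and 68 of the old ones, so ratios in this class also reflect a different mix of clusters. Chemokine and adhesion genes were higher there, with 8 of 11 members higher and a median log2 ratio of 1.08 (0.97 to 1.33, percentile 100). Ccl7 stood at 1.36 (1.19 to 1.54), Ccl2 at 1.48 and Cxcl1 at 1.08. Proliferation genes had a median of 0.94 (0.62 to 1.36), with 21 of 23 members higher. Of the 23, 13 were possible free RNA, and the other 10 had a median of 1.82. Interferon-stimulated genes had a median of 0.43 (0.24 to 0.58), with 19 of 22 higher. Isg15, a ubiquitin-like interferon product, stood at 1.36 (0.84 to 1.92). MHC class II genes had a median of 3.20 (2.63 to 3.95), with all 6 measured members possible free RNA, extracellular matrix genes one of -0.54 (-0.63 to -0.44) and immediate early genes one of -0.40 (-0.48 to -0.26). The highest single genes were Dmkn at 3.01 (2.32 to 3.80), Prg4, the joint lubricant gene, at 2.84 (2.20 to 3.56), Mrgprg at 2.38, Rdh10, an enzyme of retinoic acid synthesis, at 2.49, and Hes1 at 2.10 (1.86 to 2.36). At a finer clustering, 36 old cells and 1 young cell formed a fibroblast-like cluster led by Prg4, with Birc5 and Mki67 among its top genes against all other cells, so the ratios of Prg4 and of proliferation genes need not hold across the class. The lowest were Vps8, Cilp at -3.32 (-4.04 to -2.67), Nme2, Sparcl1 at -3.18 (-3.80 to -2.61) and the elastic fibre gene Mfap4 at -3.09 (-3.36 to -2.83). Endothelial RNA also differed in these cells: at equal depth Pecam1 was seen in 35.9% of young (29.6 to 42.5%) and 58.8% of old fibroblast-like cells (54.3 to 63.3%).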

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

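Of the tests in this part, those of handling, of free RNA of any source in EC-like cells, and of members held by another class were chosen after the results were seen. The names of pseudogenes in the first pattern had been seen before its shared sequence was predicted and searched.

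For 2 lists the medians pointed in opposite directions in EC-like and fibroblast-like cells with both counting intervals clear of 0, a difference that was not tested. Other lists with medians of opposite sign had at least 1 interval that held 0. For arterial identity and Notch genes the median log2 ratio was -0.30 (-0.36 to -0.24) in EC-like and 0.43 (0.14 to 0.76) in fibroblast-like cells. Another class held 9 of the 14 fibroblast members at over 3 times the CPM, and the other 5 had a median of -0.60. Hes1, the Notch target, was not among the 9 and stood at 197 CPM in young and 87.5 CPM in old EC-like cells, and at 73.8 and 317 CPM in fibroblast-like cells. For shear-responsive genes the medians were -0.15 (-0.22 to -0.13) and 0.23 (0.08 to 0.32), with 0.20 for the 7 fibroblast members not held by another class. In the data left out by the cell filter, 37 old barcodes (1.09% of all, 0.766 to 1.49%) took over 50% of their UMIs from haemoglobin genes. In young 0 of 1366 did, with an upper limit of 0.270%.

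A first pattern was a set of 36 genes over 2-fold lower in old in both EC-like and fibroblast-like cells, among 5438 genes with at least 100 UMIs in each. It held Vps8, Nme2, Plac9b, Rpl10-ps3 and AY036118, and 13 carried Gm-number or pseudogene names. Accession-like names such as AY036118 and Rik names are not in that count. Of the 34 genes with a searched sequence, 73.5% (55.6 to 87.1%) shared over 10% of their 3′ 50-mers with another gene, against 11.8% of the other 5265 genes. At equal UMIs per cell the median of the set stayed at -1.69. Thinning keeps each gene's expected share of a cell's UMIs, so this value cannot decide on depth. Reads shared between gene copies and counted differently in the 2 libraries may account for most of the set, but not for the 9 searched genes at or below 10%, such as Vps8 (4.10% shared), mt-Atp8, Fosb and Zbtb16, and a difference by age was not tested.

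A second pattern was the higher MHC class II expression in old EC-like cells. If free macrophage RNA carried it, the quotient of class II UMIs to UMIs of Lyz2, C1qa, C1qb, C1qc and Tyrobp would match that in macrophages, but it was 10.9 times theirs (10.3 to 11.5). The quotient was 18.6 in old EC-like cells and 23.9 in old T or NK-like cells, which mix in B cells and held 7428 CPM of class II genes. It thus speaks only against macrophage RNA, not against RNA of such other cells. Old EC-like cells held 2026 CPM of class II genes, 5.46 times (5.15 to 5.80) the 371 CPM of old fibroblast-like cells. The 5 macrophage genes stood at 109 and 103 CPM there. In young the classes held 201 and 34.7 CPM of class II genes, and 8.72 and 11.1 CPM of the macrophage genes. The quotient in young EC-like cells was 23.1. Class II and macrophage genes were thus higher in old in both classes. The 5.46 describes the level in old and cannot decide where the rise from young came from. Erythroid-like cells held 829 CPM, so free RNA remains a possible source of part of the signal. The list median was 3.04 (2.90 to 3.22) at equal depth, which cannot decide on depth, since thinning keeps each gene's expected share. It was 2.76 (2.62 to 3.07) in the 986 young and 1274 old EC-like cells without a UMI of 11 immune genes. That value argues only against doublets with immune cells in which those 11 genes are detected. None of them is on the fixed dendritic list, and Cd79a and Cd79b were each seen in 26.5% of old T or NK-like cells. Some doublets can thus pass. The screen kept 986 of 1083 young and 1274 of 2392 old cells, and also removes cells with possible free RNA such as Lyz2. A difference by age or between these 2 animals stays open.

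The last pattern was the lower immediate early expression in old EC-like cells. At equal UMIs per cell the list median was -1.20 (-1.30 to -1.13), which again cannot decide on depth. Within the 2 EC-like subpopulations, matched between libraries by their CPM of Cyp4b1, it was -1.38 and -1.23. This argues against another mix of these 2 subpopulations as the source. It does not cover a different mix of finer clusters within each of them. In fibroblast-like cells it was -0.40 (-0.48 to -0.26), lower in old but by less. These genes respond to handling, and each age was prepared once, so handling and age cannot be told apart here.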

How the results depend on the processing

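All alternatives were set before the data were examined, except the 2 subpopulations taken alone, the lists without shared or other-class members, and naming by marker detection alone. Of 359 list medians under an alternative, 283 stayed within the counting interval of the first median. A further 11 turned sign where that interval lay clear of 0, and 65 left it otherwise, some of them across 0 from a median whose interval held 0. Of 1260 ratios of named genes, 1003 stayed within the interval, 15 turned sign in that sense and 242 left it otherwise.
The EC-like share of cells, young, was 49.2% with the stricter filter and 45.0% with doublet calls kept, since the cluster led by Coch and Sost lost its name. The EC-like share of cells, old, was 58.3% with doublet calls kept, 74.2% by the per-cell marker rule, and 73.5% with the stricter filter and naming by detection alone.
The MHC class II median was 2.42 (stricter filter), 2.53 (doublet calls kept), 2.10 (per-cell marker rule), 2.79 (mean of per-cell CPM) and 2.57 (second subpopulation). The immediate early median was -1.32 (stricter filter), -1.27 (doublet calls kept), -1.38 (first subpopulation) and -1.23 (second). The matrix median was -0.64 with median-of-ratios scaling and -0.43 without members held by another class. The ratio of squared coefficients of variation was 0.958. Unthinned shares, young then old, were 16.0% and 71.4% for Cd74, 71.3% and 45.6% for Fos, and 1.57% and 17.5% for Aldh1a2.
The venous median turned negative: -0.11 (stricter filter), -0.11 (no filter), -0.20 (doublet calls kept), -0.14 (resolution 1.0), -0.12 (marker rule), -0.24 (members with at least 100 UMIs), -0.0733 (thinned), -0.10 and -0.18 (subpopulations) and -0.24 (without members held by another class). The glycolysis median was 0.0139 when thinned.
With the stricter filter Nrp2 was at -0.11, Selp 0.14, Jam2 -0.11, Csf1 0.0587 and Robo4 0.29. With doublet calls kept Selp was at 0.15, Csf1 0.0255 and Robo4 0.37. Ccl2 was at -0.91 by the marker rule, Kdr at -0.0340 when thinned and Snai2 at -0.0374 in the first subpopulation. In the second, Nr2f2 was at -0.0279, Nrp2 -0.61, Selp 0.16 and Csf1 0.0370. Some alternatives gave no ratio, with 0 young UMIs and too few old ones: Ppbp (4 old UMIs), Nrp2 (4) and Gpihbp1 (2) with doublet calls kept, and Gpihbp1 at resolution 1.0 (2) and in the second subpopulation (1). In 2 alternatives the EC-like class had lost the cluster led by Coch and Sost. That cluster held 410 young and 6 old cells with the stricter filter, and 469 young and 442 old cells with doublet calls kept. Medians and ratios under these 2 alternatives thus also compare a different set of EC-like cells. The cause of each sign change was not tested.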

Other observations

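The test of subpopulations was set before its value was seen. The ranking against fibroblast-like cells was chosen after seeing the data.

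EC-like cells of each library were also clustered apart, raising the Leiden resolution until at least 2 clusters held 15% of the cells each. This gave 2 subpopulations in each library at 0.15, a number set by that procedure, while the clustering of both libraries spread most old EC-like cells over 3 clusters. In each library the first was the subpopulation with the higher CPM of Cyp4b1, a gene left out of the correlation below. The first held 438 young and 510 old cells and expressed Foxf2, Coch, Tbx1, Sost and Adra2a. The second held 645 young and 1882 old cells and expressed Nkx2-3, Isl1, Dkk3, G0s2, Ncam1 and Plat. Coch stood at 300 CPM in the first and 30.9 CPM in the second subpopulation in young, and at 214 and 22.4 CPM in old. Nkx2-3 stood at 14.4 and 153 CPM in young, and at 46.9 and 221 CPM in old. Foxf2, Isl1 and Nkx2-3 are transcription factor genes. Bcan, higher in old EC-like cells, was a gene of the second subpopulation at both ages, with 1.25 and 26.2 CPM in young and 31.0 and 126 CPM in old. Cluster sizes are not compared between ages. Across 8078 genes, which are not independent replicates, the log2 ratio between the subpopulations in young correlated with that in old (Pearson 0.675, Spearman 0.440). Limits set beforehand, without a simulation, were below 0.2 for a split peculiar to each library and above 0.5 for a shared one, and the Spearman value lies between them. The first subpopulation was also deeper in both libraries (median UMIs 8812 and 6568 in young, 5725 and 4821 in old), which was not tested as a source of the correlation.

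Since ratios in EC-like and fibroblast-like cells correlated across 5438 genes (Pearson 0.534, Spearman 0.414), genes were also ranked by how far the EC-like ratio stood from the fibroblast-like one. Beyond the fibroblast ratio, Fmo2 was higher in old EC-like cells (log2 ratio 0.75, against -1.87 in fibroblast-like cells), as were Spock2 (0.83 and -2.16), Rftn1 (1.86 and -0.49), Fmo1 (0.75 and -1.36), Plat (0.88 and -0.53) and the nuclear receptor corepressor gene Nrip1 (0.91 and -0.58). Lower were Hes1 (-1.17 and 2.10), Ier3 (-1.15 and 0.90), Nr4a1 (-1.23 and 0.43), Egr1 (-1.15 and 0.03) and the signalling inhibitor gene Spry2 (-1.49 and 0.01).

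Aldh1a2 and Cyp26b1, both high in old EC-like cells, make and degrade retinoic acid, which induces Rarb, Dhrs3 and Tgm2 in many cells. These response genes stood at log2 ratios of -1.26 (Rarb), 0.12 (Dhrs3) and -0.11 (Tgm2).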
